A study of Xenopus laevis with 6 samples.

How the data were processed

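Gene expression was measured on Affymetrix arrays in a tissue block of preoptic area, hypothalamus and pituitary from juvenile *Xenopus laevis* frogs, with an average body weight of 0.8 g per the labels. Frogs received an injection into the brain ventricles of 0.6% saline or of recombinant *X. laevis* leptin at 20 ng per g body weight, and the tissue was taken 2 h later. There were 3 saline frogs (numbered 1 to 3) and 3 leptin frogs (numbered 4 to 6), with 1 array each. The labels number each sample as a separate frog. Per the labels' protocols, RNA was extracted with Trizol and columns, and biotinylated RNA was amplified from 250 ng of total RNA per array. The deposited values are log2 signals, 1 per probe set and array. The submitters' processing notes name RMA, affy and limma, without versions or the role of each, and other settings are not given in the sources used here. Arrays have no sequencing depth, and the number of arrays limits the precision.

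The table held 32635 probe sets. The 96 AFFX control probe sets were left out of the tests, leaving 32539. Gene symbols came from the array annotation. Of the tested probe sets, 15495 had 1 symbol, 279 had several and 16765 had none. Probe sets with several symbols or none were tested but not named. Through Entrez identifiers, 15394 annotated probe sets matched the RefSeq gene table of the assembly Xenopus_laevis_v10.1, which updated 2 symbols. That assembly served for names only, and no coordinates are given because the build behind the array annotation is not stated. *X. laevis* is allotetraploid, and the suffixes .L and .S mark the copies of a gene on its long and short chromosomes. For tests of genes and gene lists, these suffixes were removed and each gene was represented by its single-symbol probe set with the highest mean signal over the 6 arrays, which gave 9239 genes.

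The deposited log2 values were used without further normalization. Leptin was compared with saline in limma 3.58.1 under R 4.3.3 (lmFit, then eBayes with default settings), two-sided, over all 6 arrays with no covariate. Benjamini-Hochberg adjustment ran over all tested probe sets, and separately over genes, with a threshold of 0.05. Differences are given as leptin minus saline on the log2 scale with the moderated standard error (SE), and group means with the standard deviation (SD). Before the data were examined, 23 gene lists were fixed: 13 of pathways and 10 of cell type markers. The pathway lists covered JAK-STAT pathway components, cytokine feedback and STAT3 target genes, immediate early genes, and feeding and energy balance neuropeptides and receptors. They also covered thyroid hormone signalling, glucocorticoid response, inflammation, interferon response, Wnt/beta-catenin, cell cycle and DNA replication, cholesterol and fatty acid synthesis, energy sensing, and heat shock with the unfolded protein response. The marker lists covered pituitary, neurons, astrocytes and radial glia, oligodendrocytes, microglia and other leukocytes, erythrocytes, endothelium and pericytes, fibroblasts with meninges and cartilage, skeletal muscle, and choroid plexus with ependyma. Each list was tested with limma's camera, which sets the members against all other genes, at a preset inter-gene correlation of 0.01. The p-values were adjusted over the 23 lists. Camera was also run with the correlation estimated per list, and fry was run for each list. Within each list, members were also adjusted over the list alone.

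The rule for named genes was fixed with the lists. It took the 14 clearest rises and the 10 clearest falls among single-symbol genes whose groups did not overlap, with each gene represented by its non-overlapping probe set with the larger change, ordered by that probe set's p where none passed. It added *socs3*, *lepr*, *stat3*, *pomc*, *agrp*, *npy*, *cartpt*, *crh* and *trh*, and up to 4 members per list with the smallest p. Other named genes are marked as chosen after their values were seen. Values of single quantities per frog were compared with an exact permutation test, which cannot give a two-sided p below 0.1 with 3 frogs against 3.

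The steps were tested on simulated data with the means of the 32539 probe sets, in which 200 probe sets were changed. Variances were drawn at random from the distribution that limma fitted, and probe sets varied independently. This is the model that eBayes assumes, so the simulation favours recovery. With 3 arrays against 3, 68% of the probe sets changed by 1 on the log2 scale and 95% of those changed by 2 passed the adjusted threshold. The adjusted cut-off loosens as more probe sets change, so these shares hold for 200 large changes together. They do not give the chance of finding a single changed probe set. In the data, *socs3.S* differed by log2 1.00 and had a limma adjusted p of 0.306 over all probe sets. There were 7 false calls, and 0 calls when no change was set. A list shifted by a known amount passed camera, and 0 other lists did. Simulated members did not vary together, whereas the correlation estimated in the data was 0.12 for immediate early and 0.22 for cell cycle genes. The simulation therefore does not show how often camera calls lists falsely in these data. The alternatives tried were array centring, quantile and loess scaling, filters on dim probe sets, eBayes with a trend, robust or without moderation, and array weights. Others were the mean of all probe sets of a gene, other list tests, other thresholds, and leaving out each frog in turn. Covariates for pituitary hormone and skeletal muscle levels, and removal of tandem copy numbers from symbols, were added after the data were seen.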

Results

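Hybridization signals were obtained from 6 frogs, 3 given saline and 3 given leptin, to ask which genes respond in the preoptic area, hypothalamus and pituitary 2 h after leptin is injected into the brain ventricles. The median log2 signal per array lay between 7.35 and 7.45, and the correlation between arrays over all tested probe sets lay between 0.983 and 0.995. No pair of arrays shared identical values (largest share 0%). The array of leptin frog 6 stood slightly apart, with correlations of 0.983 to 0.988 with the others, which correlated with one another at 0.987 or above. The 3'/5' log2 ratio of the *gapdh* control probe sets was 0.44 ± 0.08 (SD, n = 3) in saline frogs and 0.43 ± 0.04 (SD, n = 3) in leptin frogs. The ratios of the other controls were higher in both groups. They were 1.41 ± 0.05 and 1.39 ± 0.03 for *ef1a*, and 10.2 ± 0.02 and 10.2 ± 0.11 for actin (SD, n = 3 each). The reason for the high actin ratio was not tested. Exact permutation tests (two-sided) gave p = 1 for *gapdh*, 0.6 for *ef1a* and 0.7 for actin. Since such a test cannot give less than 0.1 with 3 frogs against 3, it cannot show that the ratios differ or that they do not.

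The dissected blocks differed in pituitary hormone and muscle transcripts. Saline frog 1 had low pituitary hormone signal: growth hormone (*gh1.L*, chosen after its values were seen) was at 4.35 on the log2 scale, against 11.7 to 12.8 in the other 5 frogs. Prolactin (*prl.1.L*, chosen after its values were seen) was at 3.54 in that frog and at 12.7 to 13.4 in the others, and *pomc.L*, the precursor of ACTH and MSH, was at 9.11 against 13.9 to 14.4. In saline frog 1, *pomc.L* thus stayed above the array's median of 7.43, unlike *gh1.L* and *prl.1.L*. Saline frog 3 carried skeletal muscle transcripts, with skeletal alpha-actin (*acta1.S*) at 10.9 against 6.67 to 7.92 elsewhere and fast troponin T (*tnnt3.S*, chosen after its values were seen) at 9.09 against 3.97 to 5.56. The mean of *pomc*, *gh1* and *cga*, a measure chosen after the values were seen, was 10.4 ± 3.96 (SD, n = 3) in saline and 12.5 ± 0.18 (SD, n = 3) in leptin frogs (exact permutation p = 0.7, two-sided). The mean of 4 muscle genes, chosen in the same way, was 5.69 ± 0.18 (SD, n = 3) in leptin frogs, with a difference of -1.81 from the saline frogs, whose SD was 2.16 (n = 3) (exact permutation p = 0.2, two-sided).

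**Figure D1:**
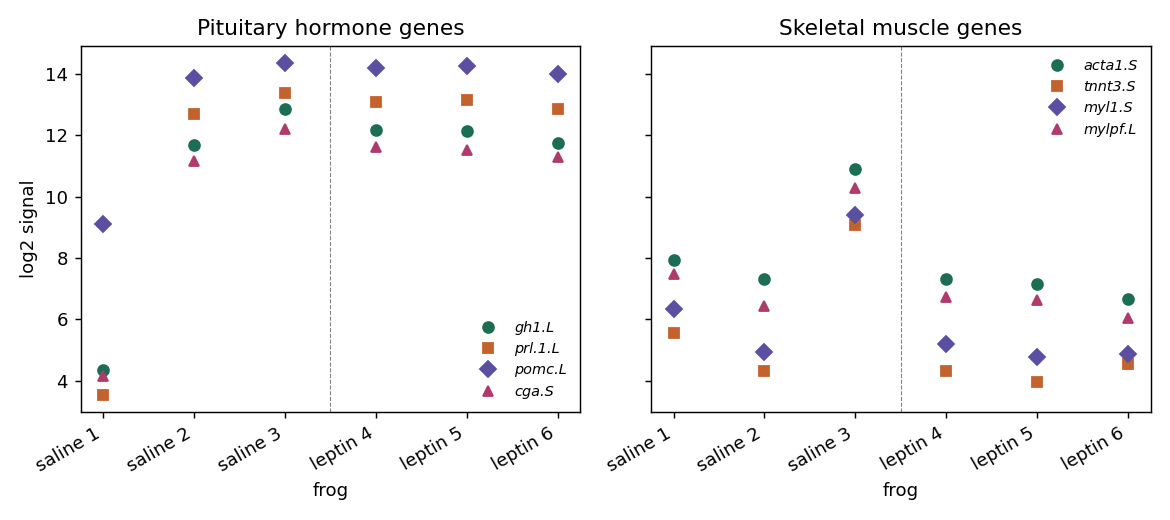
Log2 signal of 4 pituitary hormone genes (left) and 4 skeletal muscle genes (right) in each of the 6 frogs, 1 point per gene and frog, with a dashed line between saline and leptin frogs. Saline frog 1 lies at 4.35 for *gh1.L* and saline frog 3 at 10.9 for *acta1.S*, each away from the other 5 frogs.

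The clearest difference between leptin and saline frogs was in *socs3*, which encodes the suppressor of cytokine signalling that is induced by STAT3 and shuts off the leptin receptor. The *socs3.L* probe set read 5.04 ± 0.04 (SD, n = 3) on the log2 scale in saline frogs and 6.25 ± 0.15 (SD, n = 3) in leptin frogs, a 2.32-fold higher level (log2 1.21, SE 0.10). The *socs3.S* probe set was 2.01-fold higher (log2 1.00, SE 0.09), and for both copies all 3 leptin frogs lay above all 3 saline frogs. These ranked 1 and 2 by p among the 32539 probe sets. The ranks were 7 and 9 without saline frog 2, 4 and 7 without leptin frog 4, 3 and 5 without saline frog 1, 2 and 5 without leptin frog 5, and 9 and 11 without variance moderation. By mean signal the probe sets lay at percentiles 26.7 and 40.3 of all probe sets, and no measure of background was used, so the folds hold for the signals as deposited. Several immediate early genes were higher with them, among them *btg2.S* (1.86-fold), *fos.S* (1.74-fold), *nr4a1.S* (1.72-fold), *zfp36.L* (1.70-fold) and *atf3.L* (1.62-fold).

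None of these passed adjustment over all probe sets. With limma, 0 of 32539 probe sets and 0 of 9239 genes passed an adjusted p of 0.05, with the smallest adjusted p at 0.291 (*socs3.L*) and 0.174 (*socs3*), respectively. At an unadjusted p under 0.05 there were 1533 probe sets, 662 higher and 871 lower in leptin frogs, where chance gives 1627, and 452 genes, where chance gives 462. The groups did not overlap for 1676 probe sets above and 2207 below, together 11.9% against 10% by chance. When each gene was taken as the mean of all its probe sets, *socs3* alone passed over all genes (log2 1.11, limma adjusted p = 0.0365). Leaving out saline frog 2 brought 4 probe sets past the threshold, of which 2 had a symbol: *cltb.S*, chosen after its values were seen (log2 3.66), and *bglap.S* (log2 -1.63).

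Immediate early genes, which cells transcribe within minutes of stimulation, were shifted upward as a list. Of 30 measured members, 23 were higher in leptin frogs, with a mean log2 difference of 0.21 (SE between frogs 0.05) and a camera adjusted p of 4.02e-08. With an estimated correlation the adjusted p was 0.455 (unadjusted p = 0.0337). Adjusted over the list alone, 6 members rose, 0 fell and 24 did not pass, and over all genes 0 passed. The 6 were *btg2.S*, an antiproliferative factor (log2 0.90, SE 0.10), the nuclear receptor *nr4a1.L* (log2 0.72, SE 0.10), and the transcription factors *atf3.L* (log2 0.70, SE 0.10) and *fos.S* (log2 0.80, SE 0.15). The others were the MAP kinase phosphatase *dusp5.S* (log2 0.44, SE 0.09) and *ier2.L*, chosen after its values were seen (log2 0.54, SE 0.12), with limma p-values adjusted over the list alone from 0.00183 (*btg2*) to 0.0195 (*ier2*). In each of the 6, all leptin frogs lay above all saline frogs on the probe set used. The *ier2.S* probe sets had log2 differences of 0.24 (SE 0.20), with overlapping groups, and 0.42 (SE 0.15), without overlap. *btg2*, *nr4a1* and *atf3* passed in 17 of 17 alternatives, *fos* in 16, *dusp5* in 15 and *ier2* in 11. Over the list alone, *ier2* was lost without saline frog 2 (0.0700), saline frog 3 (0.0673), leptin frog 5 (0.0826) or leptin frog 6 (0.0532), and *dusp5* without leptin frog 5 (0.0597). Both were also lost with the muscle covariate, and *ier2* and *fos* without variance moderation. The mRNA-destabilizing factor *zfp36.S* had a log2 difference of 0.68 (SE 0.20) and did not pass (list-alone adjusted p = 0.0521), though it passed in 7 of 17 alternatives, array centring, quantile and loess scaling among them. The classical members *jun.L* (log2 0.07, SE 0.17) and *egr2.L* (log2 -0.10, SE 0.10) were chosen after their values were seen and did not pass. The list's mean difference was 0.20 without saline frog 1 and 0.21 without saline frog 3.

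**Figure D2:**
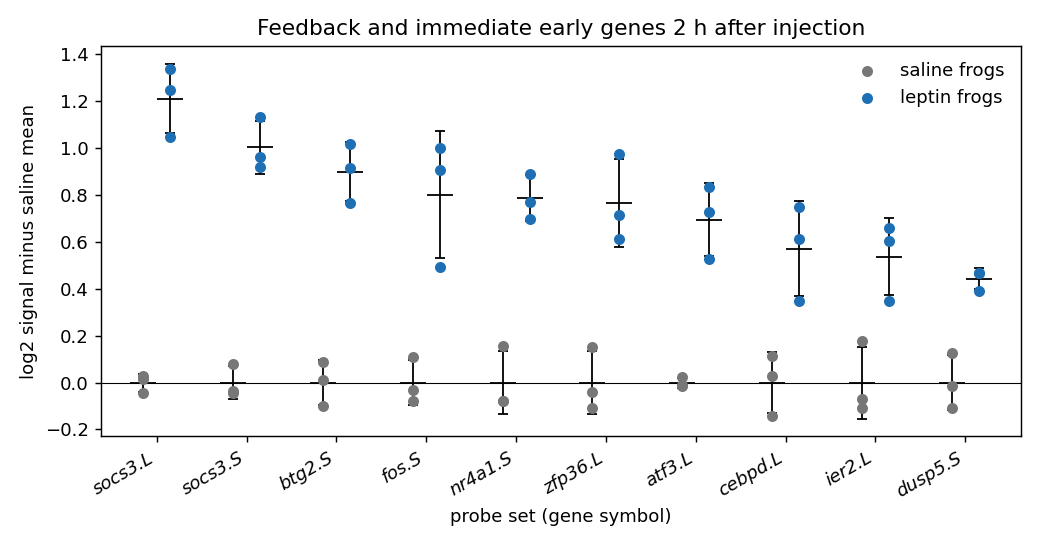
Log2 signal minus the saline mean for 10 probe sets, 1 point per frog, with horizontal bars at the group mean and whiskers of 1 SD (n = 3). Only probe sets whose groups did not overlap are shown, so the separation follows from the choice. Mean differences ran from 0.44 (*dusp5.S*) to 1.21 (*socs3.L*). Among all measured members, leptin frogs lay wholly above saline frogs in 9 of 30 immediate early genes and wholly below in 0. For cytokine feedback genes this was 3 of 19 above and 1 below.

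Cytokine feedback and STAT3 target genes also passed the list test. Of 19 measured members, 13 were higher in leptin frogs (mean log2 0.13, SE between frogs 0.05, camera adjusted p = 0.0388), and the adjusted p was 0.534 with an estimated correlation. Adjusted over the list alone, 3 members rose: *socs3.S* (adjusted p = 0.000358), *fos.S* (adjusted p = 0.0114) and the transcription factor *cebpd.L* (log2 0.57, SE 0.13, adjusted p = 0.0232). The *cebpd.S* probe sets differed less, at log2 0.12 (SE 0.10) and 0.28 (SE 0.16), and their groups overlapped. The *cebpd* call was lost without saline frog 2 (0.0937), saline frog 3 (0.0738), leptin frog 4 (0.0827) or leptin frog 5 (0.0939), and the *fos* call in this list without saline frog 2 (0.0586). Both were also lost with the muscle covariate and without variance moderation. The other 16 did not pass, including *socs2.S*, another family member of *socs3* (log2 -0.33, SE 0.11). The camera call was lost without saline frog 2 (adjusted p = 0.202), without leptin frog 4 (0.137) and without leptin frog 5 (0.107). Components of the JAK-STAT pathway itself showed no shift, with 7 of 19 members higher and 12 lower (mean log2 -0.02, camera adjusted p = 0.833), and 0 members passed over the list alone. The leptin receptor gene *lepr.S* had 2 probe sets near the low end of the signal range, at 4.96 ± 0.21 and 4.35 ± 0.13 (SD, n = 3) in saline frogs, with log2 differences of -0.01 (SE 0.19) and 0.06 (SE 0.15). The genes *stat3*, *agrp* and *crh* had no single-symbol probe set under those symbols, and *npy* shared its only probe set with another symbol. The copy annotated *stat3.2.L*, chosen after its values were seen, differed by 0.19 on the log2 scale (SE 0.30).

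Cell cycle and DNA replication genes gave the smallest list p. Of 38 measured members, 34 were higher in leptin frogs, with a mean log2 difference of 0.20 (SE between frogs 0.09) and a camera adjusted p of 5.32e-09. The adjusted p was 0.455 with an estimated correlation (unadjusted p = 0.0686). No member passed over all genes, and 0 of 38 passed adjusted over the list alone. Over the list alone, 4 members passed without leptin frog 6 and 8 with array weights, all higher in leptin frogs, with *top2a* and *aurka* among them in both. At an unadjusted p under 0.05, 7 members were higher and 0 lower, among them the mitotic kinase *aurka.L* (log2 0.37, SE 0.10), the cyclin *ccnb3.S* (log2 0.44, SE 0.12), topoisomerase *top2a.L* (log2 0.57, SE 0.16) and the spindle checkpoint kinase *bub1b.L* (log2 0.41, SE 0.15). The list mean of saline frog 3, at 7.49, lay above that of leptin frog 6, at 7.45. Saline frog 1, which had low pituitary hormone signal, had the lowest list mean at 7.27, and the mean difference was 0.14 without it.

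A further 3 lists passed camera with small shifts, and 0 of their members passed over the list alone. Endothelium and pericyte markers were higher in 12 of 12 members (mean log2 0.15, SE between frogs 0.18, adjusted p = 0.0168), led by the tight junction gene *cldn5.L* (log2 0.31, SE 0.12). Cholesterol and fatty acid synthesis genes were higher in 11 of 13 (mean log2 0.08, SE between frogs 0.13, adjusted p = 0.0194), with the elongase *elovl5.S* at 0.22 (SE 0.12) and *fdps.L* at 0.20 (SE 0.13). With an estimated correlation the adjusted p was 0.805 for both lists. Saline frog 1 had the lowest mean for each, 7.97 for the endothelium list and 10.4 for the cholesterol list. Without that frog the adjusted p was 0.309 and 0.592, with mean differences of 0.03 and -0.04. Both calls were also lost without leptin frog 4 (0.165 and 0.0941) and without leptin frog 5 (0.0892 for both). Wnt/beta-catenin genes were higher in 26 of 38 (mean log2 0.06, SE between frogs 0.04, adjusted p = 0.0388, and 0.455 with an estimated correlation). The Wnt inhibitor *dkk1.S*, the member with the smallest p, went the other way (log2 -0.49, SE 0.19). The Wnt call was kept without saline frog 2 and lost without each of the other 5 frogs, with adjusted p from 0.0684 to 0.262.

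**Figure D3:**
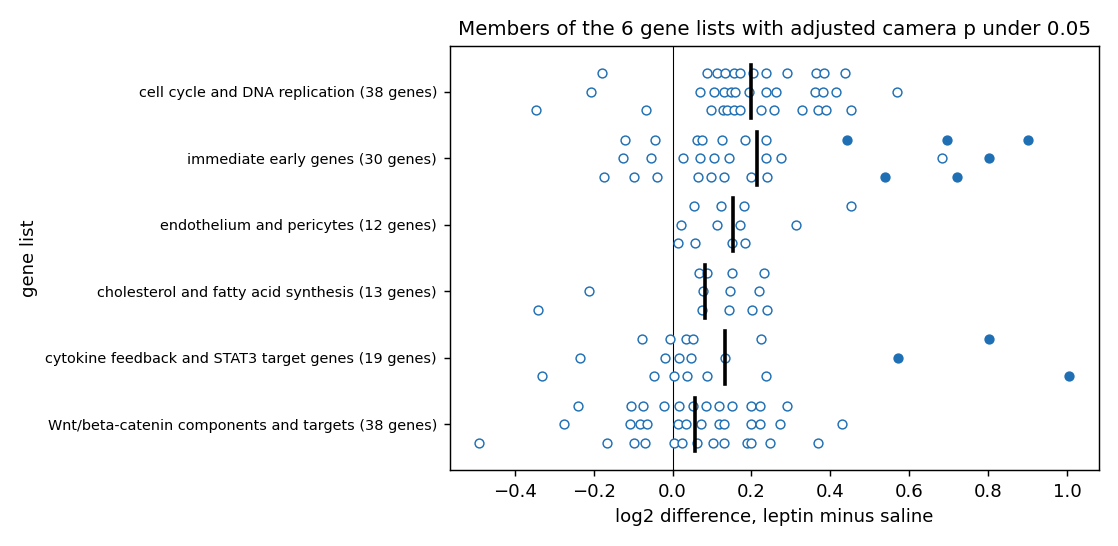
Log2 difference (leptin minus saline) of each measured member of the 6 gene lists with a camera adjusted p under 0.05, 1 point per gene and a black bar at the list mean. Filled points passed adjustment over their list alone, 6 of the 30 immediate early genes and 3 of the 19 cytokine feedback genes.

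Feeding and energy balance neuropeptides and receptors did not shift as a list (10 of 21 higher, camera adjusted p = 0.861), and 0 members passed over the list alone. The smallest p-values belonged to the opioid precursor *pdyn.L* (log2 -0.52, SE 0.14) and to urocortin 3, *ucn3.S* (log2 -0.27, SE 0.09). The anorexigenic peptide gene *cartpt.L* had a log2 difference of 0.72 (SE 0.38, limma adjusted p = 0.906 over all probe sets). The 3 *trh* probe sets differed by -0.18 (SE 0.32, *trh.S*), 0.02 (SE 0.18, *trh.L*) and -0.02 (SE 0.12, *trh.L*). The *pomc* difference of 1.70 (SE 1.32, *pomc.L*) came with the low hormone signal of saline frog 1, and for *pomc.S* it went from 1.77 (SE 1.41) to -0.02 without that frog. Neither passed. The block holds hypothalamus and pituitary together, so a *pomc* change in the hypothalamus alone cannot be read from these values.

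In the heat shock and unfolded protein list, 2 of 27 members passed adjusted over the list alone, in opposite directions, while the list did not pass (camera adjusted p = 0.543). It passed upward without saline frog 3 (mean log2 0.09, adjusted p = 0.0280) and with the muscle covariate (0.0171). The stress-responsive factor *atf3.L* rose and the inducible chaperone *hspa1a.S* fell by 0.51 on the log2 scale (SE 0.08), each at a list-alone adjusted p of 0.00757. Neither passed with the muscle covariate. The *hspa1a.S* probe set lay at percentile 26.1 of mean signal, with a limma adjusted p of 0.906 over all probe sets. Its call was also lost in the brighter 50% of probe sets, a filter that leaves out this probe set. The chaperone *hsp90ab1.S* had a log2 difference of -0.36 (SE 0.13) and did not pass. Thyroid hormone signalling and response genes had an adjusted p of 0.0793 (0.0111 in the brighter 50% of probe sets and 0.0320 with the mean of all probe sets of a gene), with 11 of 14 members higher, and the receptor *thra.L* at log2 0.30 (SE 0.08, list-alone adjusted p = 0.115). Camera adjusted p was 0.272 for glucocorticoid response genes, 0.501 for inflammation, 0.501 for interferon response and 0.664 for energy sensing. Glucocorticoid response genes passed upward without leptin frog 6 (mean log2 0.12, adjusted p = 0.0201), and interferon response genes downward without saline frog 2 (mean log2 -0.36, adjusted p = 0.0327). In none of these 5 lists did a member pass over the list alone. For energy sensing the median difference was -0.01 and the mean also below 0, while camera gave the direction up. For the neuropeptide list the median was below 0 and the mean above it.

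Among cell type markers other than endothelium, no list passed with the main settings. The pituitary list came closest (12 of 15 higher, mean log2 0.72, SE between frogs 0.69, camera adjusted p = 0.0694). Without saline frog 1, which had low pituitary hormone signal, its mean was 0.06 (adjusted p = 0.988), and without saline frog 3 it was 1.22 (adjusted p = 4.34e-05). It also passed with robust eBayes (0.0487), array weights (0.0174), the mean of all probe sets of a gene (0.0320), the muscle covariate (0.000208) and tandem copy numbers removed (0.0390). The member with the smallest p was *fshb.L*, at a log2 difference of 2.72 (SE 0.91, unadjusted p = 0.0221, list-alone adjusted p = 0.331). Skeletal muscle markers had a mean difference of -0.66 (SE between frogs 0.55, adjusted p = 0.276), with high values in saline frog 3. Their mean was -0.11 without that frog (adjusted p = 0.461) and -1.01 without saline frog 2 (0.0281). They also passed with the mean of all probe sets of a gene (-0.72, 0.00756) and with the pituitary covariate (-0.89, 0.0468), and upward with the muscle covariate (0.14, 0.0467), which is built from 4 genes of the list. Adjusted p was 0.396 for oligodendrocytes, 0.449 for neurons, 0.501 for microglia and other leukocytes and 0.501 for astrocytes and radial glia. It was 0.616 for fibroblasts, meninges and cartilage, 0.762 for choroid plexus and ependyma (median above 0, mean below) and 0.958 for erythrocytes. Leukocytes (mean -0.35) and erythrocytes (mean -0.32) passed downward without saline frog 2, each at 0.0327. Oligodendrocytes passed upward without saline frog 3 (mean 0.42, adjusted p = 0.00325) and with the muscle covariate (0.000592), and fibroblasts downward with the pituitary covariate (0.0468). In the astrocyte list, the glutamate transporter *slc1a3.L* (log2 -0.41, SE 0.12) and glutamine synthetase *glul.S* (log2 -0.40, SE 0.15) were lower without passing (list-alone adjusted p = 0.171 and 0.218). In the neuron list, the neurofilament gene *nefm.L* was higher without passing (log2 0.66, SE 0.23, list-alone adjusted p = 0.506).

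The remaining genes taken for their small p in each direction, each by its probe set with the larger change, did not pass adjustment. Higher in leptin frogs were *larp4.L* (log2 0.44, SE 0.09), *rtkn2.L* (log2 0.69, SE 0.13), the replication origin gene *orc1.L* (log2 0.42, SE 0.08), the lipid kinase *pik3c3.L* (log2 0.40, SE 0.08), *insm1.L* (log2 0.52, SE 0.11), *aplp2.S* (log2 0.57, SE 0.12) and *lin9.L* (log2 0.44, SE 0.10). Lower were *znf451.L* (log2 -0.62, SE 0.08, limma adjusted p = 0.734), *dapl1.S* (log2 -0.68, SE 0.10), *timm8b.L* (log2 -0.47, SE 0.09), *shpk.S* (log2 -0.64, SE 0.12) and the transcription factor *prdm12.L* (log2 -0.48, SE 0.10). The mitochondrial complex III subunit *uqcrfs1.S* (log2 -0.62, SE 0.13) and *XB5835883.L* (log2 -0.51, SE 0.10) were also lower. The widest differences were in the alcohol dehydrogenase *adh4.L*, at 8.55 ± 0.73 in saline and 6.42 ± 0.52 (SD, n = 3) in leptin frogs, and in *bglap.S*, at 7.77 ± 0.52 and 6.44 ± 0.07 (SD, n = 3). Both had a limma adjusted p of 0.906.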

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

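Results with the pituitary and muscle covariates or with tandem copy numbers removed come from tests chosen after the data were seen. No paired analysis was possible because the groups share no replicate numbers. Both *socs3* differences stayed positive in 32 of 32 values under the alternatives, from 0.94 to 1.29. Leaving out a frog could not reverse the sign, because the groups did not overlap. The eBayes settings and the dim filter leave a difference unchanged, so the count of positive values says little. The count of probe sets past limma's adjusted threshold was 0 and stayed within that in 18 of 20 alternatives (1533 probe sets had an unadjusted p under 0.05). It was 56 (24 higher, 32 lower) at an unadjusted p of 0.01 with 1.5-fold, a looser threshold by construction, and 0 to 4 without each frog in turn (4 without saline frog 2). The count of genes was 0 in 20 of 22 alternatives (452 genes had an unadjusted p under 0.05) and 0 without any 1 frog. It was 1 with the mean of all probe sets of a gene and 13 (6 higher, 7 lower) at the looser threshold.

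The count of lists, 6 with camera's preset correlation, was 0 with the correlation estimated and 0 with fry's directional test, both of which allow for members that vary together. Fry's mixed test takes changes in either direction. It passed cytokine feedback genes (adjusted p = 2.83e-05), immediate early genes (9.41e-05) and heat shock genes (0.000128), and no other list. Other fry values given here are from the directional test. With camera's preset correlation, the count ranged from 2 to 9 without each frog in turn, with 3 without saline frog 1 and 2 without leptin frog 4 or 5. With the correlation estimated, the adjusted p was 0.455 for immediate early genes, 0.455 for cell cycle genes and 0.534 for cytokine feedback genes, and 0.380 with fry for each. With the preset correlation and each frog left out in turn, the adjusted p ranged from 5.21e-11 to 8.12e-05, from 1.84e-13 to 1.90e-05 and from 0.00608 to 0.202, respectively. The cytokine list also missed the threshold with camera on ranks (0.208). The Wnt list missed it with arrays centred (0.0517), quantile scaling (0.0711), loess (0.0566), without the dimmest 25% (0.0930), with array weights (0.0949), with the correlation estimated (0.455), with fry (0.884), with the pituitary (0.146) or muscle (0.234) covariate, and without 5 of the 6 frogs in turn. Over the 6 lists, 90 of 126 adjusted p-values stayed under the threshold and 36 did not. Where construction does not show it, the cause was not tested.

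Of 1211 log2 differences under the alternatives, from named probe sets whose group difference is given, 1183 kept their sign and side of the threshold, 2 came to pass (*bglap.S* and *cltb.S* without saline frog 2) and 26 changed sign, none of those past the threshold. Over the frogs left out in turn, the ranges were -0.159 to 0.159 and -0.0903 to 0.164 for the 2 *lepr.S* probe sets, -0.0204 to 2.79 for *pomc.S*, -0.531 to 0.0991 for *trh.S*, -0.0988 to 0.184 and -0.0887 to 0.0998 for the 2 *trh.L* probe sets, -0.0329 to 0.243 for *jun.L* and -0.0638 to 0.497 for *stat3.2.L*. In the same order, sign changed for *lepr.S* with arrays centred (0.00306) and the pituitary covariate (0.0980), and with array weights (-0.0788). It changed for *trh.S* with array weights (0.0553) and the muscle covariate (0.141), and for *trh.L* with the pituitary covariate (-0.0407). For the other *trh.L* probe set it changed with quantile scaling (0.000652), loess (0.00108), array weights (0.0232) and the muscle covariate (0.15), which also changed *jun.L* (-0.0344) and *stat3.2.L* (-0.219). The cause was not tested. The *lepr.S* probe sets lay at percentiles 17.6 and 10.1 of mean signal, and what signal over background limits was not tested.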

Other observations

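The genes in this part were chosen after their values were seen, and all tests in it except the split count for the number of lists were chosen after the results they bear on. The homeobox gene *lhx8*, which marks cholinergic and other neurons of the subpallium, was lower in leptin frogs on each of its 3 probe sets, with log2 differences of -0.57 (SE 0.10), -0.65 (SE 0.11) and -0.72 (SE 0.16). On each of them all 3 leptin frogs lay below all 3 saline frogs, and none passed adjustment over all probe sets (limma adjusted p = 0.906). The rule for named genes takes the probe set with the larger change, whose unadjusted p was 0.00385 against 0.000961 and 0.00123 for the others, and so did not select *lhx8*.

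Other transcripts differed between frogs within a group. The pallial genes *neurod6.L* and *eomes.L* read 9.12 and 8.26 in saline frog 3, against 10.7 to 11.2 and 9.74 to 10.3 in the other 5 frogs. The midbrain-hindbrain gene *en2.L* was highest in leptin frog 6, at 7.91, and lowest in saline frog 1, at 4.86. Prostaglandin D synthase, *ptgds.S*, was at 9.70 in saline frog 1 and 10.3 in leptin frog 4, against 13.6 to 14.3 in the other 4 frogs, and the brighter *darmin.L* probe set was low in the same 2 frogs, at 8.86 and 9.34 against 13.3 to 14.1. The clathrin light chain probe set *cltb.S* read 5.37 in saline frog 1 and 5.22 in saline frog 3, and 8.91 or above in the other 4 frogs.

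For the immediate early genes, 3 explanations from single frogs were tested through the list's mean log2 difference of 0.21 (SE between frogs 0.05). It was 0.20 (SE 0.07) without saline frog 1, which had low pituitary signal, 0.21 (SE 0.07) without saline frog 3, which carried muscle transcripts, and 0.26 (SE 0.04) without leptin frog 6, whose array stood apart and whose list mean (9.46) was below those of the other leptin frogs (9.56 and 9.64). Each value exceeded 50% of the full difference by more than its SE, which argues against any of these frogs as the whole cause. Members that vary together between frogs stay open, since the camera p with the correlation estimated was 0.0337 before adjustment and 0.455 after it. A response to leptin stays open as a hypothesis, and 10 splits of the 6 frogs are too few for a share under 0.05: 1 of 10 gave as large a mean (real 0.21, highest other 0.15), and 1 of 10 as many members passing over the list alone (real 6, highest other 0), as for cytokine feedback genes (1 of 10, real 3, highest other 0). With the preset correlation, the immediate early list also passed camera in some but not all other splits. The adjusted p there was as low as 0.000222, against 4.02e-08 in the real grouping.

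For the cell cycle genes, members that vary together between frogs are a candidate explanation of the small camera p, which was 2.31e-10 with the preset correlation. With the correlation estimated, at 0.217, the p was 0.0686, as that explanation needs. The mean difference was 0.14 (SE 0.09) without saline frog 1 and 0.20 (SE 0.09) with it, so the low hormone signal of that frog, where loss of the pituitary at dissection is not known, and leptin cannot be told apart as its source at this spread. The 10 splits are too few for a share under 0.05, and 2 of 10 gave as large a mean (real 0.20, highest other 0.22). With the preset correlation, the cell cycle list also passed camera in some but not all other splits. The adjusted p there was as low as 6.30e-10, against 5.32e-09 in the real grouping. A response to leptin stays open.

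For *lhx8*, a smaller share of telencephalic and subpallial tissue in the leptin blocks could lower it, and other genes of these regions would then be lower too. Of 26 markers listed for this test, 15 were measured, 4 of them also in the neuron list, with *zic1* the brightest at a mean log2 signal of 12.0. Their mean difference was 0.0575 (SE 0.133), above 50% of the *lhx8* difference (-0.32) by more than its SE, with 7 lower, and without saline frog 3, whose pallial genes read low, it was -0.07 (SE 0.04), above -0.29 in the same way. The 6 markers taken as subpallial were *dlx2*, *dlx3*, *dlx5*, *dlx6*, *nkx2-1* and *isl1*. They had a mean of -0.17 (SE 0.04), from -0.28 (*dlx6*, limma unadjusted p = 0.0195) to 0.05 (*dlx2*), with 5 lower. Whether each of them, such as *dlx3* (-0.24), marks the subpallium in this tissue was not tested. That mean also lay above -0.32 by more than its SE. Expression of the markers elsewhere in the block was not measured and would dilute a loss of tissue. The means therefore cannot decide whether telencephalic or subpallial tissue was lost, and that explanation stays open. Loss of a smaller region around the *lhx8* cells and a response to leptin were not tested and stay open.

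For the counts, the splits are too few for a share under 0.05. The number of probe sets past limma's adjusted threshold was 0 in the real grouping and at most 2 in the others, and the number of genes was 0 and at most 1. With a real count of 0, as many in 10 of 10 splits is fixed for both and says nothing. At an unadjusted p under 0.05 the real grouping had 1533 probe sets and 452 genes. The number of gene lists past camera was 6 in the real grouping and up to 10 in the others, and 7 of the 10 splits gave as many.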
